A study of Mus musculus with 47 samples.

How the data were processed

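Whole spleens of female BALB/c mice were measured on Affymetrix mouse expression arrays after 1, 4, 7 or 14 days on a diet with *Lactobacillus brevis* KB290 or with potato starch. Per the labels' protocols, the tissue was kept in RNAlater, RNA was isolated with TRIzol and an RNeasy column, and biotin-labelled aRNA was made from 100 ng of total RNA with a 3' IVT kit, which copies from the 3' end of each transcript. The deposited values are log2 expression values per probe set, already normalized between arrays by the authors, with array medians of 6.86 to 6.87. The summarisation, normalization and software behind these log2 values are not given in the sources used here. The values run from 4.83 to 21.7, above 16, the log2 of the largest value a 16-bit scanner writes, so the highest are not plain scanner intensities. Without the array of control day 1 replicate 1 the highest value is 15.6. Direction is as deposited, but how far the summarisation compressed or stretched differences is unknown.

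All 47 arrays were assigned to 8 groups of diet and day from their titles, with 6 arrays per group and 5 for KB290 at day 7. No 2 arrays held identical values. The labels call the arrays biological replicates. Mice were housed in 4 cages per diet, and the cage of each mouse is not given in the sources used here, so each mouse was treated as independent and p-values leave out any cage effect. With 4 cages and 4 sampling days per diet, it is not excluded that each group was a single cage. Diet and cage could then not be told apart within a day.

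Probe sets were named from the platform annotation given for the array, with symbols updated through gene identifiers of the RefSeq table of assembly GRCm38.p6. Of 45101 probe sets, 34945 had 1 symbol (34754 found in the RefSeq table), 932 several and 9160 none, and a probe set with several symbols was not named. No coordinates are given because the array table names no genome build.

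The 64 control probe sets were left out, as were probe sets with a mean under the 40th percentile (6.64). Of the 27022 that remained, only those whose values ranged by at least 0.01 over the arrays were tested, which left 2615. The range filter was not part of the design fixed before the data were examined. It was added before any test because 15532 probe sets held 1 value on all arrays and 26688 more ranged by under 1e-06, which was taken as too small to compare. The fit without the range filter, as first designed, is among the alternatives. The design, the gene lists, the rule for named genes and all alternatives except the added ones were chosen before the data were examined.

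Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), in a single fit of the 8 group means, with Benjamini-Hochberg adjustment over the 2615 probe sets and a threshold of 0.05, two-sided. The contrasts were KB290 minus control on each day and averaged over days, an F test that the diet differences of the 4 days are equal, and an F test of the 4 days within each diet. Standard errors are those of limma's moderated statistic. The values are on a log2 scale already, so no pseudocount was used.

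Gene lists for spleen cell types, interferon and stress responses, proliferation and neighbouring tissues were written from textbook knowledge, 26 in all. They were tested with limma's camera on 1688 genes, each represented by its brightest probe set, with a preset correlation of 0.01. Lists with at least 5 tested members were used, 17 of the 26. That minimum was set after it was seen how many members varied, and before any list was tested. Camera was repeated with an estimated correlation, which allows for the members of a list varying together. Named genes were those passing in a comparison, or the 10 with the smallest p where fewer than 10 passed, and up to 4 members with the smallest p of each list described. A gene was represented by its brightest probe set.

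Values per array, such as control probe sets and list means, were compared between diets with two-sided exact permutation tests over all 924 splits of 6 against 6, or 462 of 6 against 5. Of 20 tests of control probe sets and 68 of list means, 0 passed after Benjamini-Hochberg adjustment. RNA quality was read from the difference between 3' and 5' probe sets of beta-actin and Gapdh. All 9 Y-linked probe sets had means of at most 6.23, below the dim filter, in these female mice.

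The steps were tested on simulated data. With 2615 probe sets and the arrays of the comparison at day 4, limma recovered 77% of 100 changes of 0.5 and 95% of 100 changes of 1, with 8 false calls, and made 0 calls with nothing changed. Rank product recovered 35% and 100%, with 48 false calls, and made 46 calls with nothing changed, so its counts are too high here. For the day effect in control mice the F test recovered 79% and 97% with 13 false calls, and for replicate numbers 96.5% of 200 changes of 0.5 with 13 false calls. Camera on 1688 genes found a proliferation list shifted by -0.3 at day 4 (adjusted p = 3.46e-10) and 0 other lists. The simulated noise was independent between genes, while the estimated correlation of the proliferation genes in the data was 0.895. These runs therefore do not show how many false calls the tests make on genes that vary together.

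Alternatives were no filter or a stricter filter on dim probe sets, other normalization, limma with a trend, robust or array-weighted spread, the replicate number as a block, 1 probe set per gene, pancreas and erythroid scores as covariates, a threshold of 0.10, only the arrays of the day, rank product, other settings of camera, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.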

Results

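Spleen RNA was profiled on 47 Affymetrix mouse expression arrays from female BALB/c mice on 1 of 2 diets. One diet contained lyophilised *Lactobacillus brevis* KB290, a lactic acid bacterium, and the control diet contained 5.8% (w/w) potato starch in its place. Mice were sampled on days 1, 4, 7 and 14 of feeding, with 6 arrays per diet and day except for KB290 at day 7, which had 5. This gave 24 control and 23 KB290 arrays, each from a separate animal by its label. The number of arrays limits the precision. The same spleens were also sampled for a cytotoxicity assay, which is not analysed here.

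The deposited log2 values were close to constant for most probe sets. Of 45101 probe sets, 15532 held a single value on all arrays, and 94.0% varied by less than 0.01 over the arrays. The comparisons therefore rest on 2615 probe sets, which represent 1688 genes. How the remaining differences were scaled by the summarisation is not given in the sources used here, so differences are reported on the deposited log2 scale and need not equal differences in RNA amount. The median standard error of a diet difference at day 1 was 0.10.

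At day 1 of feeding, the comparison asks what a single day on KB290 does to the spleen. No probe set passed in limma (0 of 2615), with 61 at an unadjusted p under 0.05, of which 47 were lower with KB290, and 16 calls by rank product. Genes of neutrophils and their precursors lay lower with KB290 in 11 of 11 measured genes, with a median difference of -0.76. Among them Camp, the cathelicidin precursor, was 10.63 ± 0.83 (SD, n = 6) with control diet and 9.34 ± 1.34 (SD, n = 6) with KB290. The difference was -1.28 (SE 0.54) for Camp, -1.18 (SE 0.51) for the neutrophilic granule protein Ngp, and -0.87 (SE 0.35) and -0.76 (SE 0.30) for the granule proteases Prtn3 and Ctsg. Camp, Ngp and Prtn3 were below the control mean in 5 of 6 KB290 mice and Ctsg in 4 of 6. The neutrophil score of single mice was 9.92 ± 0.61 and 9.17 ± 0.82 (SD, n = 6 each), with exact permutation p = 0.0996. Control replicate 1, an array with pancreas signal described below, had the highest control score, 10.8 against 9.08 to 10.27. As a group the neutrophil genes passed in limma's camera (adjusted p = 1.13e-13), with adjusted p = 0.154 with an estimated correlation. In limma no member passed over all genes, and 0 passed adjusted over the list alone (smallest adjusted p = 0.0694). Rank product, which made 46 calls on simulated data with nothing changed, called 7 of the 11 lower, namely Ngp, Camp, Ltf, Mpo, Ctsg, Prtn3 and Lcn2.

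Other gene lists also passed at day 1. The 5 platelet and megakaryocyte genes were all lower (median -0.24, adjusted p = 0.00270, and adjusted p = 0.428 with an estimated correlation), for example Tubb1 at -0.27 (SE 0.18). The 8 red pulp and marginal zone macrophage genes were all higher (median 0.08, adjusted p = 0.00739, and adjusted p = 0.538 with an estimated correlation), with the complement gene C1qb at 0.26 (SE 0.13). Ribosomal protein genes were higher in 7 of 7 (median 0.02, adjusted p = 0.00739) and respiratory chain genes in 6 of 7 (median 0.05, adjusted p = 0.00741), and both had adjusted p = 0.428 with an estimated correlation. Control replicate 1 lay below the other control arrays for both, with means of 12.84 against 12.96 to 13.00 and 11.30 against 11.46 to 11.53. Without the 2 arrays with pancreas signal, of which it is 1, these lists had camera adjusted p = 0.827 and adjusted p = 0.106. Cox5a, a cytochrome c oxidase subunit, was higher by 0.15 (SE 0.05). The 12 pancreas genes were all lower (median -2.20, adjusted p = 2.55e-14, and adjusted p = 0.154 with an estimated correlation). Their control mean was carried by a single array, control day 1 replicate 1, and Prss2 for example was 9.07 ± 5.61 (SD, n = 6) with control diet against 6.71 ± 0.08 (SD, n = 6) with KB290. In none of these lists did a member pass in limma over all genes or by rank product, or adjusted over the list alone. In total 6 of 17 lists passed, and 2, the neutrophil and plasma cell lists, passed without control day 1 replicate 1. The neutrophil list passed in all 12 runs that left out 1 array (largest camera adjusted p = 9.47e-06). These runs kept the preset correlation of 0.01, while the estimated correlation of this list was 0.808. They therefore do not allow for its genes varying together. The 18S ribosomal RNA control was also lower with KB290 on this day (-0.50, exact permutation p = 0.0541). The 10 genes with the smallest p in limma, none passing, included Zc3h15 at -0.35 (SE 0.11), Zfp91 at -0.25 (SE 0.08) and the collagen gene Col3a1 at -0.29 (SE 0.11), which passed adjusted over the list alone in the stroma list (adjusted p = 0.0498), a list that did not pass as a group (adjusted p = 0.720).

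At day 4, 9 probe sets differed between the diets, and all 9 were lower with KB290. They represent 6 named genes, and 2 of them carry no gene name. Knl1, a scaffold of the kinetochore, was 7.37 ± 0.39 (SD, n = 6) in control mice and 6.59 ± 0.35 (SD, n = 6) in KB290 mice. Its difference was -0.78 (SE 0.16, limma adjusted p = 0.00965). Secisbp2l, a relative of the selenocysteine insertion factor, was 7.92 ± 0.27 and 7.21 ± 0.27 (SD, n = 6 each), a difference of -0.72 (SE 0.13, limma adjusted p = 0.00155). Hnrnpu, an abundant nuclear RNA-binding protein, differed by only -0.08 (SE 0.02, limma adjusted p = 0.0372) between groups at 9.87 ± 0.04 and 9.78 ± 0.02 (SD, n = 6 each). The others were named after their values were seen. A probe set of Gabpb2, a subunit of the GA-binding transcription factor, was lower by -0.62 (SE 0.11, limma adjusted p = 0.00155), and one of the centrosomal gene Cep350 by -0.78 (SE 0.18, limma adjusted p = 0.0372). A pair of probe sets of Malat1, a nuclear long noncoding RNA, differed by -0.76 (SE 0.15) and -0.59 (SE 0.14). For each of the 9 probe sets, 6 of 6 KB290 mice lay below the control mean.

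**Figure D1:**
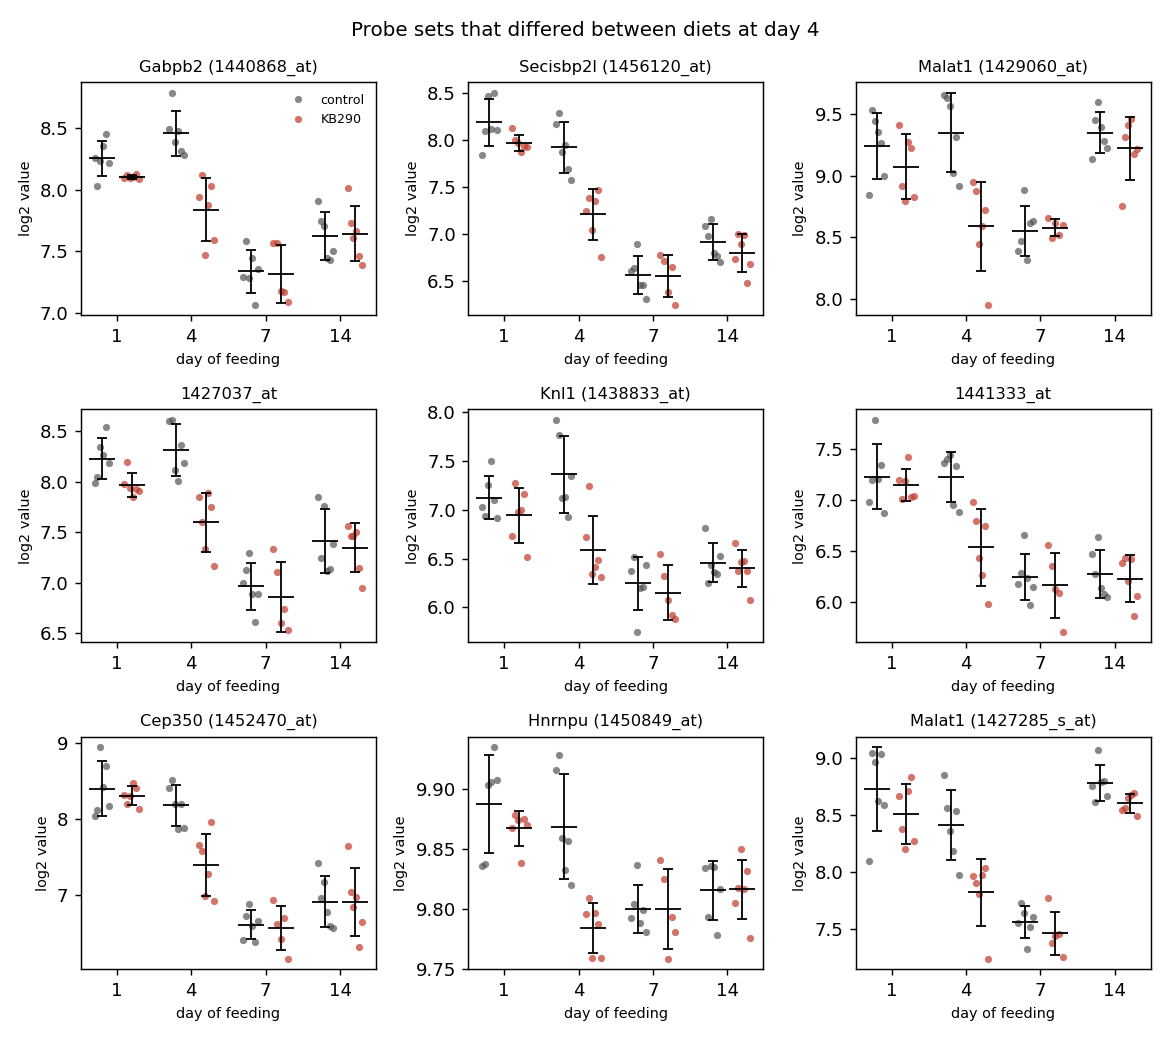
Log2 values of the 9 probe sets that differed at day 4, per array (points), by day of feeding and diet, with the group mean (bar) and SD (whiskers). At day 4 Secisbp2l is at 7.92 in control mice and 7.21 in KB290 mice, and at day 7 it is at 6.56 and 6.55. These day 7 means lie below 6.64, the level of the dim filter. So do the day 4 KB290 means of Knl1 (6.59) and of a probe set without a gene name (6.54). Whether low signal limits differences there was not tested.

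The other tested probe sets of these genes did not pass in limma at day 4, while rank product called 4 more of Malat1, all lower. The brighter probe sets of Gabpb2 and Cep350 were at -0.16 (SE 0.10) and -0.11 (SE 0.09), and a dimmer one of Hnrnpu at -0.22 (SE 0.23). Malat1 had 7 tested probe sets, all lower, from -0.12 (SE 0.12) to -1.19 (SE 0.29), and its brightest was at -0.67 (SE 0.17, limma adjusted p = 0.0672). Just short of the threshold in limma were also the ubiquitin ligase gene Nedd4 at -0.84 (SE 0.21), the Kit ligand gene Kitl at -0.38 (SE 0.10), Isoc1 at -0.31, the proteasome gene Psmb7 at -0.26, Tbc1d15 at -0.49 and Zfp91 at -0.30, with adjusted p from 0.0656 to 0.0752. For each of these genes 6 of 6 KB290 mice lay below the control mean. Of the 218 probe sets at an unadjusted p under 0.05, 188 were lower with KB290.

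Among the gene groups at day 4, proliferation genes had the smallest p. All 27 measured proliferation genes were lower with KB290 (median -0.36, camera adjusted p = 3.98e-05, and adjusted p = 0.781 with an estimated correlation). Cenpe, the kinetochore motor, was 8.74 ± 0.55 and 7.81 ± 0.41 (SD, n = 6 each), a difference of -0.94 (SE 0.29), and the proliferation marker Mki67 was at -0.75 (SE 0.42), Bub1 at -0.56 (SE 0.27) and Cdc20 at -0.18 (SE 0.10). All 23 erythroid genes were also lower (median -0.34, adjusted p = 0.0134, and adjusted p = 0.877 with an estimated correlation), among them the erythroid transcription factor Klf1 at -0.49 (SE 0.36), Rhag at -0.45 (SE 0.32) and Cldn13 at -0.57 (SE 0.37). In the other direction, 8 of 8 red pulp and marginal zone macrophage genes were higher (median 0.11, adjusted p = 0.000877, and adjusted p = 0.580 with an estimated correlation). C1qb was 10.78 ± 0.13 and 11.14 ± 0.23 (SD, n = 6 each), a difference of 0.35 (SE 0.13), with 6 of 6 KB290 mice above the control mean. Also higher were 8 of 8 interferon gamma response genes (median 0.09, Irf1 at 0.18), 8 of 8 B cell genes (median 0.10, Ebf1 at 0.16), 5 of 5 plasma cell genes (median 0.12, Mzb1 at 0.14) and 5 of 5 stroma genes (median 0.20, Tagln at 0.24). These 4 lists each had adjusted p = 0.0134. With an estimated correlation, adjusted p = 0.781 for the interferon gamma and B cell lists and adjusted p = 0.580 for the plasma cell and stroma lists.

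In limma no list member passed at day 4 over all genes, and 0 passed adjusted over the list alone (smallest adjusted p = 0.0577 for proliferation and 0.0669 for the macrophages). Among members of the lists that passed, rank product called 4 of 27 proliferation genes lower (Cenpe, Mki67, Bub1 and Cenpf), 5 of 23 erythroid genes lower (Cldn13, Icam4, Kel, Klf1 and Rhag) and Igha higher. In total 7 of 17 lists passed, and 4 passed without control day 4 replicate 1. On that array the erythroid and proliferation scores were 10.87 and 10.35, and the B cell and macrophage scores 10.09 and 10.22. On KB290 day 4 replicate 5 they were 9.93 and 9.37, and 10.61 and 10.74. Scores of different lists can thus move together, and whether the 7 lists are separate differences was not tested. With the preset correlation, the proliferation, macrophage and plasma cell lists passed in all 12 runs that left out 1 array. The erythroid list was lost in 4 of them, the interferon gamma list in 3, the B cell list in 2 and the stroma list in 1. The list scores of single mice overlapped between the diets, with exact permutation p = 0.0866 for proliferation. Between same-numbered arrays of day 4 the proliferation score was lower with KB290 in 6 of 6, by 0.01 to 0.74, with an exact permutation p = 0.0312 from sign flips within numbers, the smallest that 64 sign flips can give, and 0.354 after Benjamini-Hochberg adjustment over the 17 lists, a test chosen after the values were seen.

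**Figure D2:**
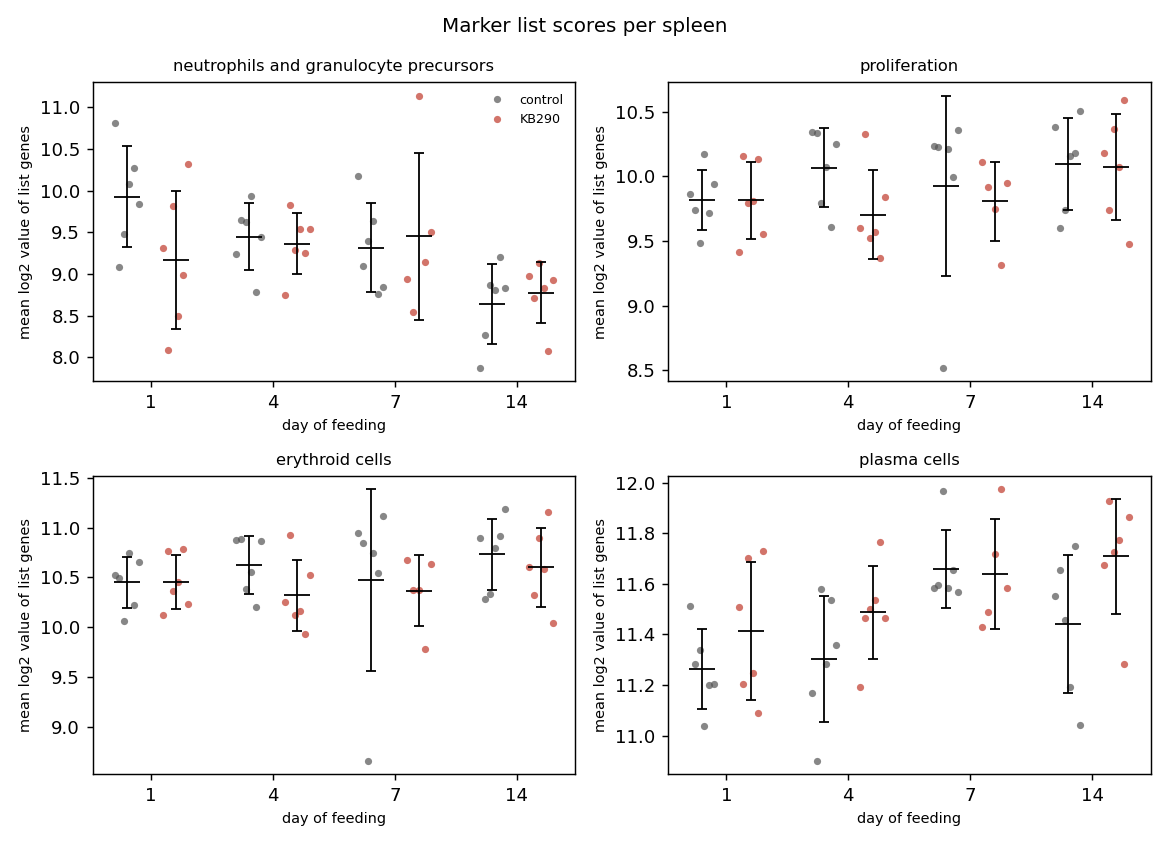
Mean log2 value of the genes of each marker list per spleen (points), by day of feeding and diet, with the group mean (bar) and SD (whiskers). The proliferation score at day 4 was 10.07 with control diet and 9.70 with KB290, and the neutrophil score at day 1 was 9.92 and 9.17.

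The count of 9 at day 4 moved with the arrays and the fit. It was 3 without control replicate 1 or 2 or KB290 replicate 3 or 6, and 5 without control replicate 3 or 5 or KB290 replicate 4. It was 17 without control replicate 6, 20 without KB290 replicate 2 and 32 without KB290 replicate 5. It was 0 in a fit of the 12 arrays of that day alone, 42 with the replicate number as a block, 494 with array weights, 24 without the range filter and 86 by rank product. The 18S control was lower with KB290 on the same day, at 11.08 ± 0.46 and 10.38 ± 0.39 (SD, n = 6 each), a difference of -0.70 with exact permutation p = 0.0173, and 0.346 after Benjamini-Hochberg adjustment over 20 such tests. It was also lower with KB290 on every other day, at -0.50 on day 1, -0.27 on day 7 and -0.29 on day 14. The exact permutation p on those days was 0.0541, 0.532 and 0.310.

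At day 7 no probe set passed in limma (0 of 2615), with 10 at an unadjusted p under 0.05 and 7 calls by rank product. The smallest p belonged to an immunoglobulin light chain gene, Igkv6-14, at 8.62 ± 0.23 (SD, n = 6) in control mice and 9.36 ± 0.42 (SD, n = 5) in KB290 mice. Its difference was 0.74 (SE 0.20), with 5 of 5 KB290 mice above the control mean, and it did not pass in limma (adjusted p = 0.998) but was called by rank product. Mzb1, a chaperone of antibody-secreting cells, was at 0.17 (SE 0.09), with 5 of 5 KB290 mice above the control mean, and did not pass. In the other direction, the 3 probe sets of Igha were at -0.46 (SE 0.50), -0.48 (SE 0.51) and -0.44 (SE 0.49), none passing. The plasma cell list did not pass (camera adjusted p = 0.250). The proliferation genes were again lower in 27 of 27 (median -0.11, camera adjusted p = 0.000481) and the erythroid genes in 22 of 23 (median -0.10, adjusted p = 0.00272), both with adjusted p = 0.793 with an estimated correlation, for example Cenpe at -0.32 (SE 0.30) and the haem synthesis gene Fech at -0.25 (SE 0.26). Interferon gamma response genes were higher in 8 of 8 (median 0.12, adjusted p = 0.0424), with Cxcl9 at 0.19 (SE 0.12). Heat shock genes were higher in 12 of 12 (median 0.11, adjusted p = 0.0408), with Hsph1 at 0.34 (SE 0.37). These 2 lists also had adjusted p = 0.793 with an estimated correlation, and 0 members of the 4 passed in limma over all genes, by rank product or adjusted over the list alone. Of 17 lists 4 passed. The number was 2 without control replicate 4 or 5 or KB290 replicate 5, 1 without control replicate 6 and 7 without KB290 replicate 3. All 12 pancreas genes were higher (median 0.64, adjusted p = 0.160), carried by KB290 replicate 4. Without that array and control day 1 replicate 1, the proliferation list had adjusted p = 0.60, the erythroid list 0.882 and the interferon gamma list 0.301, while the heat shock list passed with 0.00164. Control replicate 3 had an erythroid score of 8.66 against 10.54 to 11.12 and a proliferation score of 8.52 against 9.99 to 10.36 on the other control arrays, and without it these lists had adjusted p = 3.82e-11 and adjusted p = 2.68e-10, the interferon gamma list 0.0221, and the heat shock list no longer passed (adjusted p = 0.151). Of the 11 runs that left out 1 array, the interferon gamma list was lost in 9, the heat shock list in 5, the erythroid list in 4 and the proliferation list in 3. Heat shock genes also went with the replicate number, and the KB290 arrays of this day hold no number 6. With the number as a block the heat shock list had adjusted p = 1.08e-05, proliferation 0.00106 and erythroid 0.00889, and the interferon gamma list no longer passed (adjusted p = 0.0717).

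At day 14 no probe set passed in limma (0 of 2615), with 7 at an unadjusted p under 0.05 and 15 calls by rank product. Igha, the constant region of the IgA heavy chain, had the smallest p of any gene. It was 10.66 ± 1.31 (SD, n = 6) with control diet and 12.02 ± 0.74 (SD, n = 6) with KB290, a difference of 1.36 (SE 0.49) that did not pass in limma (adjusted p = 1.00), although rank product called all 3 of its probe sets. All 6 KB290 mice were above the control mean, and its other 2 probe sets were at 1.36 and 1.30. Igha was the 1 plasma cell gene that passed adjusted over the list alone (adjusted p = 0.0427). The plasma cell list passed upward (adjusted p = 0.0422, and adjusted p = 0.894 with an estimated correlation) with a mean of 0.27 but a median of -0.01, and no longer passed with the replicate number as a block (adjusted p = 0.102). Its other members were near 0, with Jchain at 0.03 and Mzb1 at -0.02. Red pulp and marginal zone macrophage genes were lower in 7 of 8 (median -0.09) and erythroid genes in 21 of 23 (median -0.11), both with adjusted p = 0.0188. With an estimated correlation these had adjusted p = 0.894 and adjusted p = 0.994. Examples are the growth factor receptor gene Csf1r at -0.17 (SE 0.09) and the haem synthesis gene Alas2 at -0.26 (SE 0.23). In limma none of the members of these lists passed over all genes, and none in the macrophage and erythroid lists passed adjusted over the list alone or was called by rank product. Of 17 lists 3 passed. The number was 0 without KB290 replicate 2 and 1 without control replicate 5 or KB290 replicate 1 or 3. Of the 12 runs that left out 1 array, the plasma cell list was lost in 9, the macrophage list in 7 and the erythroid list in 6. KB290 replicate 1 stood apart in RNA quality, with 3' to 5' differences of 0.957 for beta-actin and 1.13 for Gapdh against 0.44 to 0.55 and 0.49 to 0.59 on the others of its group.

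Averaged over the 4 days, no probe set differed between the diets in limma (0 of 2615, smallest adjusted p = 0.167). At an unadjusted p under 0.05 there were 229, of which 172 were lower. With array weights 322 passed, with the replicate number as a block 18, and with pancreas and erythroid scores as covariates 3. The genes with the smallest p were Zfp91 at -0.17 (SE 0.04), Secisbp2l at -0.27 (SE 0.06), Igkv6-14 at 0.36 (SE 0.10) and Knl1 at -0.28 (SE 0.08). Of 17 lists 4 passed. All 27 proliferation genes (median -0.12, camera adjusted p = 0.00414) and all 23 erythroid genes (median -0.13, adjusted p = 0.00556) were lower, both with adjusted p = 0.695 with an estimated correlation. All 5 plasma cell genes (median 0.08, adjusted p = 0.00556) and 7 of 8 macrophage genes (median 0.05, adjusted p = 0.0342) were higher, with Igha at 0.48 (SE 0.25) and C1qb at 0.19 (SE 0.06). These also had adjusted p = 0.695 with an estimated correlation, and none of the members of the 4 lists passed in limma over all genes. C1qb alone passed adjusted over the list alone (adjusted p = 0.0468). Without the 2 arrays with pancreas signal only the plasma cell list passed (adjusted p = 0.00395), with proliferation at 0.0871 and erythroid at 0.136. Without KB290 day 7 replicate 3, 7 lists passed.

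Whether the diet difference changed between days was tested directly. No probe set passed this interaction in limma (0 of 2615), with 17 at an unadjusted p under 0.05, and 4 passed with array weights. Secisbp2l, Psmb7, Knl1 and Hnrnpu had the smallest p (0.00159 to 0.0130, adjusted p = 1.00). A difference at day 4 that is absent at other days is therefore not shown by the test. The lists of type I interferon response, T cell, immediate early and glucocorticoid response genes passed in none of the diet comparisons, with adjusted p of 0.558 to 0.822, 0.224 to 0.575, 0.283 to 0.527 and 0.352 to 0.527.

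The genes tied most closely to cell-mediated cytotoxicity could not be compared. The probe sets of Ifng, Prf1, Gzmb, Ncr1, Klrk1, Cd69, Il12b, Tnf and Il10 varied by at most 7e-09 over all 47 arrays. None of 15 natural killer cell genes on the array varied by 0.01 or more, and of 19 cytotoxic granule and death ligand genes only Gzma, Ctsc and Srgn did. Ctsc, the protease that activates granzymes, was higher with KB290 at day 4 by 0.17 (SE 0.08, unadjusted p = 0.0410, limma adjusted p = 0.558). Granzyme A (Gzma) was at 0.10 (SE 0.06) and serglycin (Srgn) at 0.04 (SE 0.04) on that day, and none of the 3 passed in a diet comparison in limma or was called by rank product. Measurable members were also too few for a group test in the lists of type 1 cytokine genes (2 of 20), pattern recognition and NF-kB genes (2 of 26), Th2, Th17 and regulatory T cell genes (0 of 17), germinal centre B cells (0 of 9), dendritic cells (1 of 11), circadian clock genes (1 of 18) and adipose tissue (4 of 11, 3 tested). None of their tested members passed in a diet comparison in limma. Rank product called the adipose list member Car3 on all 4 days, lower on days 1 and 14 and higher on days 4 and 7, and none of the others.

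Far more genes differed between sampling days than between diets, although the sampling day cannot be told apart from a batch of array processing. In control mice 1709 of 2615 probe sets differed between the 4 days (65.4%, 1086 genes) and in KB290 mice 1647 (63.0%, 1047 genes). With a score for the pattern that goes with replicate numbers as a covariate 1014 and 891 passed, and without the range filter 10502 and 10807. Both diets shared 1569, against 1076 for independent lists. Against day 1, 166 probe sets passed at day 4 in control mice, 1553 at day 7 and 1354 at day 14, and in KB290 mice 80, 1489 and 1277. Most were higher, 1021 of the 1553 in control mice at day 7. The genes with the smallest p included the co-chaperone gene Dnaja2, which rose in control mice from 10.41 ± 0.07 at day 1 to 10.94 ± 0.09 at day 7, and in KB290 mice from 10.45 ± 0.04 to 10.94 ± 0.08 (SD, n = 6 or 5). Thrap3 rose from 9.31 ± 0.18 to 10.05 ± 0.08 between days 1 and 14 in control mice, and Xist, the noncoding RNA of the inactive X chromosome, from 11.75 ± 0.10 to 12.42 ± 0.16. Secisbp2l fell from 8.19 ± 0.25 at day 1 to 6.56 ± 0.20 at day 7 and Kitl from 8.43 ± 0.17 to 7.35 ± 0.13 in control mice. Slc25a30, Zfp106, Iws1, Ankrd13a and Golph3 completed the 10 in control mice, and Macf1, Eif3a, Eif5b and Parp1 were among the 10 in KB290 mice.

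The marker lists varied in how many members differed between days, set against 65.4% of all tested probe sets in control mice and 63.0% in KB290 mice, and no list test was run for day. In each diet 7 of 8 B cell genes passed, with a median difference of day 14 from day 1 of 0.44 with control diet and 0.41 with KB290. Neutrophil genes were lower at day 14 than day 1 in 11 of 11 genes in both diets, by a median of -1.25 in control mice, where 8 of 11 passed, and -0.36 in KB290 mice, where 1 of 11 passed. The KB290 median was -0.14, with 8 of 11 lower, without day 1 replicate 6, and -0.24 without day 1 replicate 3. At day 7 they were higher than at day 1 in 0 of 11 genes in control mice (median -0.68) and in 10 of 11 in KB290 mice (median 0.30). The KB290 value rests on day 7 replicate 3, with a neutrophil score of 11.14 against 8.55 to 9.50 on the others, and without it 3 of 11 were higher (median -0.08). It was 0.09 and 0.15 without day 1 replicate 2 or 4, and 0.45, 0.53 and 0.61 without day 1 replicate 3 or 6 or day 7 replicate 2. No gene passed the test of a difference between the diets in these changes. Heat shock genes passed in 5 of 12 with control diet and 6 of 12 with KB290, and immediate early genes in 5 and 4 of 7. T cell genes passed in 0 of 6 in both diets, erythroid genes in 1 and 0 of 23, and platelet and megakaryocyte genes in 1 and 0 of 5. The bioB spike-in, a bacterial transcript added before hybridisation, was at 10.23 ± 0.39 on day 1 and 7.98 ± 0.28 on day 14 in control mice and at 10.12 ± 0.17 and 8.19 ± 0.50 in KB290 mice (SD, n = 6 each), which was not tested between days. This transcript does not come from the mice, so its lower level marks a difference in processing or normalization between arrays of these days.

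**Figure D3:**
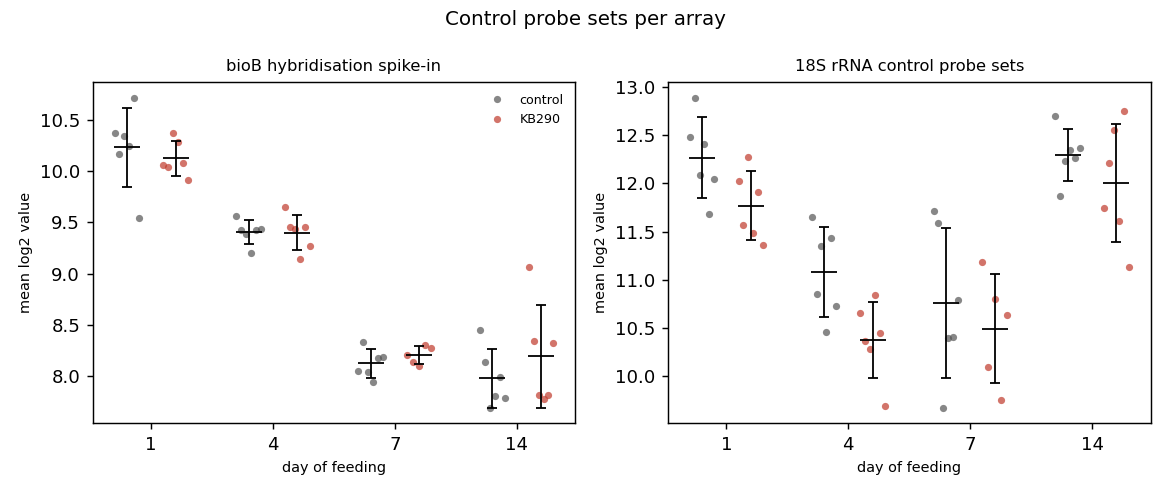
Mean log2 value of control probe sets per array (points), by day of feeding and diet, with the group mean (bar) and SD (whiskers). The bioB spike-in lay at 10.2 at day 1 and 7.98 at day 14 in control mice, and the 18S control was 11.1 and 10.4 in control and KB290 mice at day 4.

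Within groups, expression went with the replicate number in the sample labels. An F test over the 6 numbers, with the 8 groups in the fit, passed for 719 of 2615 probe sets (27.5%, 486 genes). Of the 10 genes with the smallest p, 5 were in the heat shock list, namely Dnaja1 (limma adjusted p = 9.69e-10), Hsph1, Dnajb1, Hspa1b and Chordc1, and the others were Ylpm1, Khdc4, Zfand2a, Ubqln1 and Phc3. The mean deviation of Hspa1b, the inducible Hsp70, from its group means was -0.98 for arrays numbered 1 and 1.89 for arrays numbered 6. Of the lists, 8 of 12 heat shock genes passed, 5 of 7 immediate early, 6 of 8 interferon gamma response and 5 of 8 red pulp and marginal zone macrophage genes, against 0 of 27 proliferation, 0 of 23 erythroid and 0 of 11 neutrophil genes. Each diet held the same numbers on each day, apart from the 1 array fewer at day 7.

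**Figure D4:**
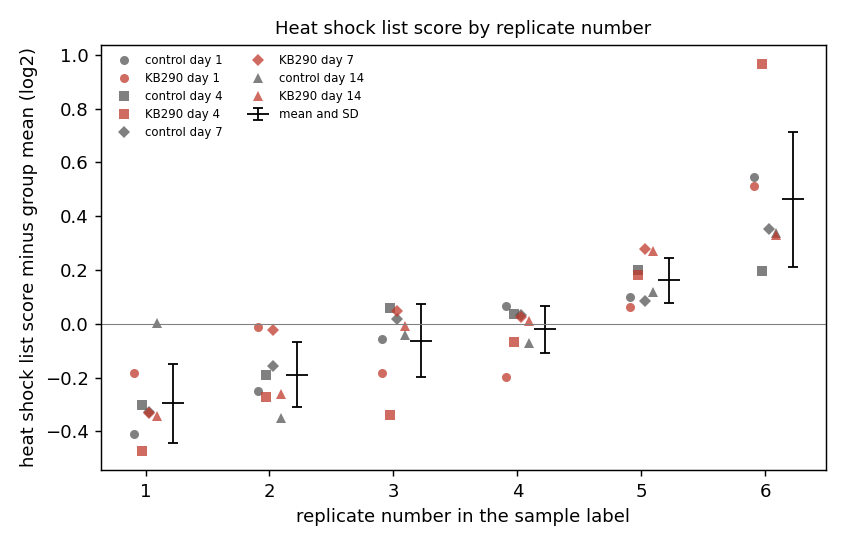
Mean log2 value of the 12 heat shock genes minus the mean of the array's group, per array (points), against the replicate number in the sample label, with the mean (bar) and SD (whiskers) of each number. Arrays numbered 1 lie at -0.30 on average and those numbered 6 at 0.46.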

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

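The tests of the heat shock score, of pancreatic tissue or a swapped sample, of the position between days, of the 18S control, of array-weighted splits and of splits within replicate numbers were chosen after the results were seen. Of 154 groups of array values checked for a sample far from the others, 16 held such a sample, where chance gives about 7.7.

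Exocrine pancreas genes were far above all other arrays on control day 1 replicate 1, with a list mean of 19.5 against 6.56 to 6.68 on the other arrays of its group, and on KB290 day 7 replicate 4, at 9.82 against 6.54 to 6.87. On control day 1 replicate 1, 100% of the 19 pancreas genes that vary had their highest value, led by Cpb1 at 21.3 (median of 45 other arrays 5.68), Cpa1 at 20.7 and Prss2 at 20.5. Of the 19, 18 had their next highest value on KB290 day 7 replicate 4, where Cpb1 was 12.1. Of 3 spleen cell scores, 2 lay within the range of the other arrays on control day 1 replicate 1 (T cells at 8.97, macrophages at 10.24) and B cells at 9.78 lay below their lowest, 10.09, which argues against a sample of another tissue. Pancreatic tissue taken with the spleen may be the source, as a hypothesis, and no biological explanation was tested.

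Samples that stood apart for other genes were mostly the same few. On control day 1 replicate 1 the ribosomal protein mean was 12.84 and the respiratory chain mean 11.30, below the others of the group. On control day 7 replicate 3 the erythroid mean was 8.66 against 10.54 to 11.12, the proliferation mean 8.52 against 9.99 to 10.36, the plasma cell mean 11.97 against 11.57 to 11.65, the respiratory chain mean 11.36 and the Gapdh 3' to 5' difference 0.279. On KB290 day 14 replicate 1 the 3' to 5' differences were 0.957 for beta-actin and 1.13 for Gapdh, above the others. The ribosomal protein mean was 13.00 on KB290 day 7 replicate 1 and 12.98 on control day 14 replicate 2, and the respiratory chain mean 11.43 on KB290 day 7 replicate 4. The heat shock mean was 10.79 on KB290 day 1 replicate 6, and a Malat1 probe set was 7.23 on KB290 day 4 replicate 6, below 7.81 to 8.03 on the others.

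The 9 probe sets lower with KB290 at day 4 were weighed against technical explanations. The tables argue against the axis along which replicate numbers differ as the whole cause (as a covariate it left the median size at 0.959 of its value, all 9 passing). Leaving out any single array of day 4 kept the median size at 0.874 or more, so no single array carried the whole difference. The probe sets were called on these same arrays, so this size could hardly fall far. The calls numbered 3 to 32 in these runs, so a single array is not excluded as the reason that some passed. The calls run along the direction of day: all 9 were also lower at day 7 than day 1 in control mice, as were 85.1% of the 188 probe sets lower at day 4 at an unadjusted p under 0.05, against 38.5% of all tested. Yet the day 4 arrays of the diets did not differ detectably on the axis from day 1 to day 7 (exact permutation p = 0.396), and with that axis as a covariate the ratio was 0.890 with all 9 passing, which argues against a position between the days as the whole cause and leaves a part open. The authors' normalization stays open: normalizing the deposited values again left the ratio at 0.992 or more, but moved the mean of the tested probe sets by at most 0.059 on any array and does not undo the authors' step. A factor tracked by the 18S control also stays open: with it as a covariate the ratio was 0.901, but 2 of the 9 passed, as the median difference went from -0.71 (SE 0.15) to -0.64 (SE 0.16). The rule for this test first used the ratio alone, which would have argued against the 18S control, and the condition on how many stay past the threshold was added after its outcome was seen. The KB290 diet is the biological explanation the design gives and may contribute, which is a hypothesis, and cages were not separable from it.

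For splits of the same arrays, 100 drawn per result, 4 reached the 9 calls at day 4, the real one included. That share is just under 0.05, but it comes from 100 drawn splits and is 1 of 13 counts tested so, so it does not exclude chance. The highest other split gave 291, so the samples hold structure beyond diet. Of the 32 splits that exchange the diets within replicate numbers at day 4, which allow for the structure by number, 1 reached 9, the real one (highest other 2), and 1 reached the 42 calls with the number as a block (highest other 3), the smallest share these splits can give. A fit of the arrays of that day alone made 0 calls. The 494 calls with array weights at day 4 were reached in 30 splits (highest other 1667), so chance is not excluded. These splits ignore the replicate number, as do those of the list counts below, and splits within numbers were not run for either. For the 0 calls at day 1, 7 and 14, averaged over days and in the interaction, the splits decide nothing, since all 100 must reach a count of 0 (highest other 224, 359, 136, 0 and 546). For the day effects only the real split was as large, in control mice (1709, highest other 983) and in KB290 mice (1647, highest other 795). That is the smallest share 100 drawn splits can give, which argues against chance but does not exclude it among 13 counts. For the numbers of lists passing chance is not excluded: 53 splits for the 6 lists at day 1 (highest other 9), 15 for the 7 at day 4 (9), 58 for the 4 at day 7 (10), 73 for the 3 at day 14 (8) and 76 for the 4 averaged over days (11). Besides the real split, 99, 94, 93, 87 and 98 drawn splits passed at least 1 list in these comparisons.

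The 719 probe sets that differ by replicate number exceeded those of random numbering within groups (1 of 100 draws as large, the real one included, highest other 580). With spike-in levels as covariates 600 passed, which argues against hybridisation strength as the whole cause. Spike-ins added before hybridisation cannot show how well each sample was labelled, so labelling strength stays open. With the 3' to 5' differences of the controls as covariates 519 passed, which leaves RNA degradation as a partial cause undecided. The heat shock score differed by number (permutation p = 1e-05, the smallest that 100000 permutations can give), with 7 of 7 arrays numbered 6 above and 7 of 8 numbered 1 below their group means. An order of dissection or handling may lie behind the numbers, which the labels do not say, and no biological explanation was tested because the numbers are no group of the design.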

How the results depend on the processing

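The fits without the range filter, with a stricter range filter, without the 2 arrays with pancreas signal and with the axis of replicate numbers as a covariate were chosen after the data were seen. For 148 values of named genes in the diet comparisons, other settings gave 2183 values, of which 2096 kept their direction and side of the threshold, 17 lost and 65 gained a pass and 5 reversed. Leaving out arrays gave 2660, of which 2599 kept both, 36 lost and 16 gained a pass and 9 reversed. The causes were not tested. Pseudocount alternatives were not run because the values are on a log2 scale as deposited. The comparisons are limited to genes whose deposited values vary. Whether low signal over background is the reason was not tested, and of 27022 probe sets above the dim level only 2615 varied enough to be tested.

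For the diet effect at day 4, with 9 calls, there were 494 with array weights, 86 by rank product, 63 with the axis of replicate numbers as a covariate, 42 with pancreas and erythroid covariates, 32 at a threshold of 0.10, 24 without the range filter, 2 with 1 probe set per gene and 0 with only the arrays of that day. Leaving out 1 array gave 3 to 32. With 0 calls at days 1, 7 and 14, rank product gave 16, 7 and 15, and the fit without the range filter gave 1 at day 1 and 5 at day 7. The diet effect averaged over days, with 0 calls, had 322 with array weights and 3 with pancreas and erythroid covariates. The interaction, with 0 calls, had 4 with array weights and 1 without the range filter. All of these 0 counts stayed 0 when 1 array was left out. For days 1, 7 and 14 only the arrays of that day were left out in turn, and for the average and the interaction all 47. The day effects in control and KB290 mice, 1709 and 1647, were 10502 and 10807 without the range filter, where more probe sets were tested, 1014 and 891 with the axis of replicate numbers, and 1084 and 1046 with 1 probe set per gene, where fewer were tested. Leaving out 1 array gave 1642 to 1792 and 1563 to 1676. The counts without the range filter exceed the 2615 probe sets of the main fit, so many near-constant probe sets also went with day.

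With the replicate number as a block, the diet effect at day 4 had 42 calls and the average over days 18, and no other count moved by over 1.5 times. The numbers do not pair the samples over the study. The correlation of deviations between same-numbered control and KB290 arrays was over 0.1 in 1 of 6 pairs at day 1, 6 of 6 at day 4 (0.28 to 0.72), 4 of 5 at day 7 and 3 of 6 at day 14. A sample correlated best with its own number in 1, 4, 2 and 3 of these pairs, a hint from the data and not from the design.

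The numbers of gene lists passing on days 1, 4, 7 and 14 and averaged over days were 6, 7, 4, 3 and 4, and with an estimated correlation 0, 0, 0, 0 and 0. Without the 2 arrays with pancreas signal, 2 lists passed at day 1 and 1 averaged over days. Leaving out 1 array gave 2 to 7, 4 to 7, 1 to 7, 0 to 4 and 3 to 7 lists. With the block 6, 7, 3, 2 and 4 passed, the interferon gamma list being lost at day 7 and the plasma cell list at day 14.

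Reversed values were small. At day 14, Txndc5 was at 0.00108 with quantile normalization and 0.0572 with array weights, and Slc40a1 at 0.0190 with array weights. At day 4, Psmb8 was at -0.00762 with pancreas and erythroid covariates, and at day 1 Rpl8 was at -0.00360 without the pancreas arrays. Leaving out 1 array gave -0.00360 to 0.0645 for Rpl8 at day 1, -0.363 to 0.0387 for Bpgm at day 7, and at day 14 -0.0578 to 0.0502 for Txndc5, -0.0722 to 0.00797 for Mzb1 and -0.160 to 0.00999 for Slc40a1.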

Other observations

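The comparisons of values below were chosen after the data were seen, and they carry no test. Across the 2615 probe sets, which are not independent replicates, the diet differences of days 4 and 7 correlated at r = 0.51, with the same sign in 72.6%, although the 2 days share no mice. Days 4 and 14 correlated at 0.30 (same sign in 59.3%) and days 7 and 14 at 0.25 (62.6%). Day 1 correlated at 0.14 with day 4 (65.5%), 0.10 with day 14 (58.3%) and -0.40 with day 7 (60.1%), the last being the pair of days that each hold an array with pancreas signal. Of the 9 probe sets that passed at day 4, 2 also passed by replicate number.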
